A study of Rattus norvegicus with 4 samples.

How the data were processed

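Per the labels, primary cells from the cerebral cortex of Sprague Dawley rat embryos at embryonic day 16 were cultured for 24 h on 4 hydrogels, named SFMA, N-SFMA, L-SFMA and NL-SFMA, with 5 parallel wells per hydrogel and 100000 cells per well. These names are the samples' titles. The treatment labels of the L-SFMA and NL-SFMA samples write L@SFMA and NL@SFMA, and both spellings were taken to mean the same hydrogel. Whether the RNA of the wells was pooled is not given in the sources used here, nor is what the letters N and L stand for. The labels describe poly(A) RNA, 1.5 µg of input, NEBNext Ultra RNA libraries and sequencing on an Illumina NovaSeq instrument, with 1 library per hydrogel.

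For each library the authors listed 18755 genes with a raw read count and an FPKM value. The deposited count column holds whole numbers, described in the submitters' processing notes as made with HISAT2, with no version given, and HTSeq 0.13.5. The deposited FPKM column is the count divided by the length of the gene model and by the library's summed count, with the usual scale factor. This was checked by recovering the gene model lengths from both columns, which gave whole numbers to within 1e-06 bases. The submitters' notes name a rat build beside a human one without a role for either. Alignment settings, the strand setting of the counting and any filters are not given in the sources used here. No genome coordinates are reported.

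The gene lists, the size rule, the rule for named genes and a first set of alternative settings were chosen before the data were examined. Differences between libraries are log2 ratios of FPKM with a pseudocount of 1 FPKM, which understates the ratio of genes with low values. The 12394 genes with an FPKM of at least 1 in at least 1 library were tested. With 1 library per hydrogel there is no spread between replicates, so genes at least 2-fold higher or lower on this scale were counted and no p-value is given for a pair of libraries. Folds printed for single genes are ratios of CPM (the count over the library's summed count) without a pseudocount, with an exact (Clopper-Pearson) 95% interval conditional on both counts. The intervals, and the floor of 3 counts for a gene listed at 0 (0.171 to 0.212 CPM), cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The number of 2-fold calls from counting error alone was estimated from 100 random draws per comparison.

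Of the 29 gene lists, with 774 genes of which 747 were found, 28 had at least 5 tested members: cell-cell adhesion (cadherins, catenins and the immunoglobulin superfamily), integrins and focal adhesion, extracellular matrix, axon growth, neurotrophic factors and receptors, excitatory cortical neurons, inhibitory interneurons, radial glia and neural progenitors, cell cycle, synapse, astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelial cells and pericytes, erythroid cells, immediate early genes, unfolded protein and integrated stress response, heat shock, p53 and apoptosis, hypoxia and glycolysis, oxidative stress response, cholesterol synthesis, cytokines, Wnt targets, YAP and SRF targets, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, and mitochondrially encoded genes. The list of meningeal fibroblasts had 2 tested members of 18 and was not tested. A list's median log2 difference was placed among 10000 random lists of the same size matched on expression in 20 bins. A list is said to stand apart when its percentile is under 2.5 or over 97.5. The percentile describes these libraries and is not a test between hydrogels. Members past 1.5-fold were counted. Some genes are in more than 1 list.

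Named genes needed an assigned symbol and an FPKM of at least 5 in the higher library. They were the 10 largest differences each way against SFMA, the 5 largest each way for NL-SFMA against N-SFMA and L-SFMA, up to 10 genes per letter with the largest difference shared by both pairs of libraries, up to 4 members with the largest difference per list described, and 8 genes fixed because the series concerns cell-cell adhesion and neural growth (Cdh2, Ctnnb1, Ncam1, L1cam, Gap43, Tubb3, Map2 and Dcx).

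The hydrogel names were read as 2 factors, N and L, which assumes that each letter means the same modification in both names that hold it. An additive model of both factors was fitted to the counts of all 4 libraries with edgeR 4.0.16 (quasi-likelihood, TMM scaling, Benjamini-Hochberg 0.05). The test fixed beforehand was limma 3.58.1 (trend, robust) on log2(FPKM + 1), when FPKM alone was assumed. It is given beside edgeR, which fits the deposited counts. The model has 1 residual degree of freedom, which is how far the N effect differs with and without L (the N by L interaction). No spread between replicate cultures enters it. The common dispersion from edgeR was 0.0408, with the same trended variance for every gene. Shared N or L differences were also compared as correlations across genes, against 4 libraries simulated with counting error alone. Genes are not independent replicates, so these have no p-value.

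Alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter or a filter at 5 FPKM, centring on the median gene, rescaling to TPM, leaving out mitochondrial, ribosomal protein and haemoglobin genes, the mean of a list, and limma without trend or robust fitting. Alternatives chosen after seeing the data were removal of the gene length trend (a lowess curve on log2 model length with a span of 0.3), random lists also matched on length (5 expression by 10 length bins), CPM with a pseudocount of 0.5, TMM scaling of the size rule, relative log expression factors and DESeq2 1.42.0. In simulated data with 12394 genes, the size rule found 85 of 88 genes changed 2.5-fold and 84 of 84 changed 4-fold, with 6 false calls. The edgeR model found 36 of 100 genes changed 2-fold and 99 of 100 changed 4-fold, with 4 false calls. Its simulated counts had the same dispersion for every gene, close to what the fit assumes. They held no length trend and no N by L interaction, so few false calls were built in. Neither these counts nor the simulation of the size rule give the error rate in the real libraries, which have no replicates. Of 140 unshifted simulated lists 4 stood apart, as did 29 of 30 lists shifted by 0.6. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

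No genome was at hand for GC content, so it was not analysed here. Genes without an assigned symbol (3096) were kept in counts and not named. Values of some single genes that the rule selects are not reported here.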

Results

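RNA from embryonic rat cortical cells was measured after 24 h on 4 hydrogels, SFMA, N-SFMA, L-SFMA and NL-SFMA, with 1 library each. The series asks how a cell-cell adhesion cue in a hydrogel acts on neural growth. Summed read counts were 17553098 for SFMA, 15429180 for N-SFMA, 16340264 for L-SFMA and 14172205 for NL-SFMA. Genes with at least 1 read numbered 16963, 16691, 17156 and 16399 in the same order. There was no replicate library, so no difference between hydrogels could be checked against a spread between replicates.

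The genes fixed in advance for adhesion and neural growth differed in the following way. Cdh2, the neural cadherin that joins neighbouring cells, was at 63.2 FPKM on SFMA, 83.7 on N-SFMA, 97.3 on L-SFMA and 154 on NL-SFMA. Its fold against SFMA was 1.32 (95% counting interval 1.27 to 1.38), 1.54 (1.48 to 1.60) and 2.44 (2.36 to 2.53). The neuronal adhesion molecules Ncam1 (33.8, 64.1, 79.5 and 105 FPKM) and L1cam (21.0, 40.9, 51.2 and 47.4 FPKM) were higher in the other 3 libraries than in SFMA. So were the neuronal cytoskeletal genes Map2 (24.7, 56.5, 61.1 and 98.0 FPKM) and Dcx (68.3, 140, 161 and 266 FPKM). Ctnnb1, which encodes the cadherin partner beta-catenin, was at 253, 259, 263 and 322 FPKM. The growth cone gene Gap43 was at 83.7, 86.7, 70.7 and 79.7 FPKM. The neuronal tubulin Tubb3 was at 1882, 2602, 1957 and 1659 FPKM. Gap43 and Tubb3 on L-SFMA and NL-SFMA against SFMA, and Ctnnb1 on N-SFMA and L-SFMA, change sign under at least 1 other scaling or with the length trend removed.

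**Figure D1:**
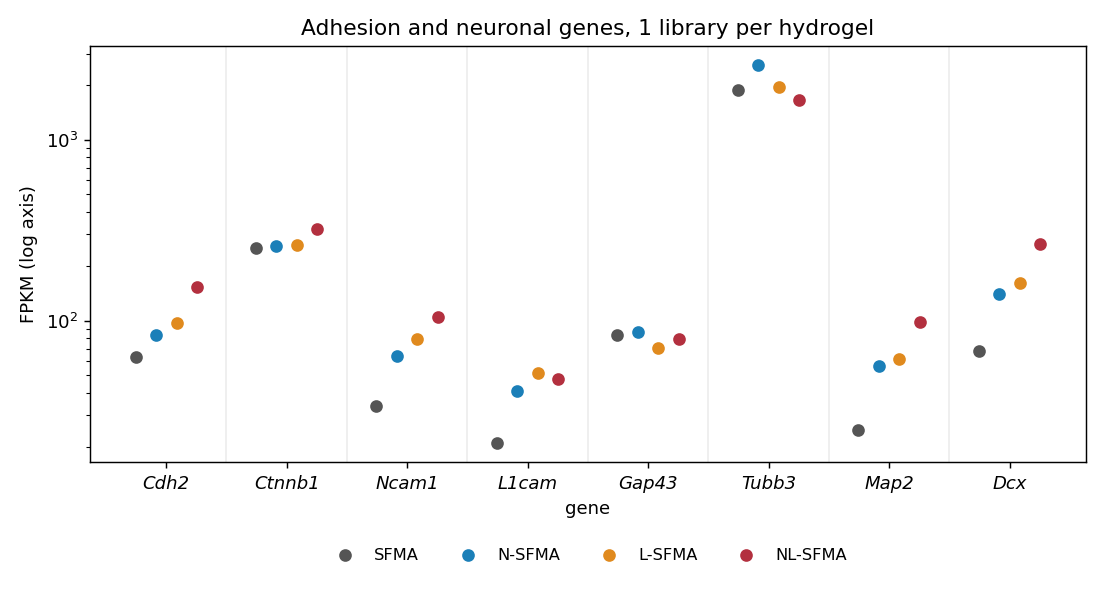
FPKM on a log axis for 8 genes fixed in advance, with 1 point per library and colours for the hydrogels. Cdh2, Ncam1, Map2 and Dcx are lowest in SFMA and highest in NL-SFMA, with Cdh2 between 63.2 and 154 FPKM.

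A trend with gene length ran through the comparisons with SFMA. Across genes, the log2 difference correlated with log2 model length at r = 0.46 for N-SFMA, 0.53 for L-SFMA and 0.50 for NL-SFMA. Genes are not independent replicates. In NL-SFMA the median difference was -0.89 for 890 genes under 1 kb and 0.92 for 650 genes over 8 kb. The corresponding medians were -0.46 and 0.43 in N-SFMA and -0.58 and 0.68 in L-SFMA. The read-weighted median length of the gene models was 2851 bases in SFMA, 3278 in N-SFMA, 3438 in L-SFMA and 3626 in NL-SFMA. With this trend removed, the log2 differences from SFMA, in the order N-SFMA, L-SFMA and NL-SFMA, were 0.24, 0.41 and 0.93 for Cdh2, 0.50, 0.65 and 0.71 for Ncam1, 0.67, 0.89 and 0.56 for L1cam, 0.77, 0.73 and 1.09 for Map2 and 0.62, 0.65 and 1.04 for Dcx. Values of single genes and lists elsewhere are without this removal unless it is named.

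**Figure D2:**
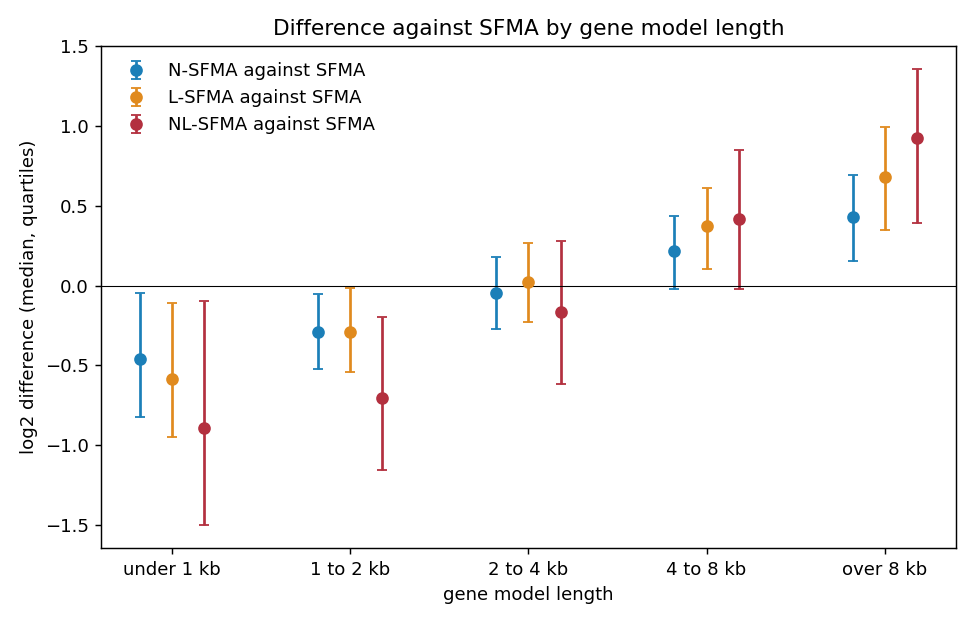
Log2 difference against SFMA (vertical axis) by gene model length in 5 bins (horizontal axis), as the median and quartiles of the genes in each bin. In all 3 comparisons the median is below 0 under 1 kb and above 0 over 8 kb, reaching 0.92 in NL-SFMA.

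N-SFMA against SFMA asks what accompanies the N modification alone. The list medians of axon growth, cell-cell adhesion, synapses and excitatory neurons were higher on N-SFMA, and those of radial glia and astrocyte markers were lower. Most members of the higher lists were not past 1.5-fold. The adhesion list had a median log2 difference of 0.46 over 43 tested members, with 15 of them past 1.5-fold higher and 0 lower. Its largest differences were L1cam (0.93), the cadherin Dchs1 (0.91), the axonal contactin Cntn2 (0.91) and Ncam1 (0.90). The axon growth list had a median of 0.47 over 50 members, with 20 past 1.5-fold higher and 1 lower, led by the microtubule-associated gene Map1b (1.55) and the semaphorin receptor Plxna4 (1.24). Synaptic genes had a median of 0.39 (38 members, 7 higher), among them the vesicle calcium sensor Syt1 (0.91) and its relative Syt4 (0.78). Excitatory neuron genes had a median of 0.28 (21 members, 5 higher), including the transcription factor Mef2c (1.10). Removing the length trend gave an adhesion median of 0.10 with 3 of 43 members past 1.5-fold higher, at percentile 97.49, which no longer stood apart, although the list did so among random lists matched on length (99.99). The other medians were then 0.36 for axon growth (14 higher, 1 lower), 0.17 for synapses (4 higher) and 0.29 for excitatory neurons (2 higher), and Plxna4 (0.71), Dchs1 (0.44) and Ncam1 (0.50) were nearer to SFMA.

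Radial glia genes had a median of -0.55 on N-SFMA, with 10 of 25 past 1.5-fold lower and 1 higher. The radial glial lipid carrier Fabp7 (-2.47), the glutamate transporter Slc1a3 (-1.64) and the outer radial glia gene Hopx (-1.05) were lower, while Eomes, a factor of intermediate progenitors, was higher (1.08). Astrocyte genes had a median of -0.64 (8 of 14 lower), including Id3 (-1.22), Mlc1 (-0.84) and Slc1a3, which with Sox9 stands in both lists. Cell cycle genes had a median of -0.50 (13 of 32 lower, 1 higher), led by Ube2c (-1.17) and the mitotic kinase Cdk1 (-1.08). Immediate early genes, which respond within minutes to stimulation, had a median of -0.80 (12 of 19 lower), including Fos (-3.20), Nr4a1 (-2.56), Atf3 (-1.05) and Jun (-1.03). Oxidative stress genes had a median of -0.59 (11 of 21 lower), led by the metallothioneins Mt3 (-2.92), Mt2A (-2.68) and Mt1 (-1.62), close paralogs whose reads may be shared. Microglia genes had a median of -0.63 (6 of 9 lower), including Tyrobp (-1.66) and Lyz2 (-1.64). Endothelial and pericyte genes had a median of -0.53 (1 of 5 lower). Erythroid genes had a median of -1.17 (7 of 8 lower), and haemoglobin genes held 0.152% of the reads in SFMA and 0.0456% in N-SFMA. Ribosomal protein genes had a median of -0.67 (28 of 45 lower) and nuclear-encoded oxidative phosphorylation genes -0.37 (12 of 38 lower), lists with median model lengths of 1133 and 1547 bases. Removal of the length trend gave medians of -0.39 for ribosomal proteins (12 of 45 lower), -0.17 for oxidative phosphorylation (6 of 38) and -0.29 for oxidative stress (7 of 21). Hopx (-0.71), Id3 (-0.83), Ube2c (-0.80), Cdk1 (-0.78) and Atf3 (-0.86) were then less than 2-fold lower.

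By the size rule 106 genes were at least 2-fold higher and 328 lower on N-SFMA, where counting error alone gave 2.91 and 3.49 on average. The largest differences upward were Map1b (2.96-fold, 2.90 to 3.02), the dynein motor gene Dync1h1 (1.55 on the log2 scale), Ank2 (1.40), Tro (1.38), Nbea (1.38), Mycbp2 (1.31), Macf1 (1.30), Ank3 (1.27), Prkaa2 (1.26) and Ubr4 (1.26). All of these but Tro and Prkaa2 have gene models over 12 kb in this table. Map1b (1.00), Tro (1.78) and Prkaa2 (1.25) were also past 2-fold with the length trend removed, while the other 7 lay between 0.48 for Macf1 and 0.98 for Dync1h1. Downward, the thyroid hormone transporter Slco1c1 was 34.1-fold lower (20.8 to 60.1), the FGF target Etv4 29.7-fold lower (18.9 to 49.7), the neural progenitor factor Sox3 6.80-fold lower (5.92 to 7.84) and the glial lipid carrier Fabp7 5.65-fold lower (5.26 to 6.08). The FGF pathway inhibitor Spry4 (-2.86), Fos, Mt3, Mt2A, Nr4a1 and the embryonic globin Hbe1 (-2.76) complete these 10. With the length trend removed, 185 genes were lower in place of 328, and 45 of the higher and 160 of the lower genes were called both ways. Of the 14 lists that stood apart, 12 also did so among random lists matched on length; endothelial cells and oxidative phosphorylation did not.

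L-SFMA against SFMA asks the same of the L modification alone. The adhesion, synapse, axon growth and excitatory neuron lists were again higher, and the radial glia list did not stand apart. Adhesion genes had a median of 0.62 with 23 of 43 past 1.5-fold higher and 0 lower, led by Dchs1 (1.52), Cntn2 (1.44), the cadherin Celsr3 (1.37) and L1cam (1.25). Synaptic genes had a median of 0.61 (19 of 38 higher), among them the active zone gene Bsn (1.46). Axon growth genes had a median of 0.57 (25 of 50 higher, 2 lower), including the receptors Plxna4 (1.87), Plxna2 (1.67) and Nrp1 (1.54). Excitatory neuron genes had a median of 0.51 (9 of 21 higher), including the upper-layer factor Cux2 (1.15). Corrected for the length trend, the medians were 0.25 for adhesion (11 of 43 higher), 0.28 for synapses (7 of 38), 0.30 for axon growth (17 of 50, 3 lower) and 0.47 for excitatory neurons (8 of 21). Dchs1 (0.87), Celsr3 (0.66), L1cam (0.89), Bsn (0.73) and Cux2 (0.86) were then less than 2-fold higher.

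Lower lists on L-SFMA were led by erythroid genes (median -1.69, 7 of 8 lower) and ribosomal protein genes (-0.97, 45 of 45 lower, including Rps29 at -1.95). Haemoglobin genes held 0.0256% of the reads, and ribosomal protein genes 3.06% against 5.85% in SFMA. Oxidative phosphorylation genes had a median of -0.65 (22 of 38 lower), led by Cox7c (-1.42). Cell cycle genes had a median of -0.52 (12 of 32 lower, 1 higher), including Ube2c (-1.16) and Ccnb2 (-1.03). Immediate early genes had a median of -0.50 (8 of 19 lower, 1 higher), with Fos at -2.67 and Nr4a1 at -2.46. Oxidative stress genes had a median of -0.48 (9 of 21 lower) and microglia genes -0.46 (3 of 9 lower). Cytokine and chemokine genes had a median of -0.43 (6 of 16 lower), led by Cxcl2 (-1.33) and Ccl3 (-1.10). Oligodendrocyte lineage genes had a median of -0.40 (2 of 7 lower, 1 higher), with the lineage factor Olig1 at -1.28. Astrocyte genes had a median of -0.34 (3 of 14 lower, 1 higher). Radial glia genes had a median of -0.15 (percentile 7.23), although Fabp7 (-2.14) and Slc1a3 (-1.32) were lower here too. The radial glia median was -0.31 with the length trend removed, which stood apart as lower, and the other medians were then -0.53 for ribosomal proteins (17 of 45 lower), -0.34 for oxidative phosphorylation (7 of 38), -0.29 for oxidative stress (6 of 21) and -0.21 for astrocytes (3 of 14). Ube2c (-0.62), Ccnb2 (-0.77), Cxcl2 (-0.83) and Ccl3 (-0.48) were then less than 2-fold lower.

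By the size rule 412 genes were at least 2-fold higher and 377 lower on L-SFMA, where counting error alone gave 2.88 and 3.18. The largest upward were the lipoprotein receptor Lrp1 (4.11-fold, 3.88 to 4.35), Plxna4 (4.44-fold, 4.10 to 4.82), the cadherin Fat4 (4.50-fold, 4.16 to 4.88), Macf1 (1.74), Map1b (1.71), Sorl1 (1.70), Ank2 (1.70), Plxna2 (1.67), Tulp4 (1.61) and Mycbp2 (1.61), all with models over 7 kb. Of these, Fat4 (0.96), Macf1 (0.58), Map1b (0.94), Ank2 (0.85) and Mycbp2 (0.78) were less than 2-fold higher with the length trend removed. Downward were Hbe1 (24.0-fold, 12.4 to 53.1), Slco1c1 (30.4-fold, 19.3 to 50.9), Etv4 (16.2-fold, 11.6 to 23.2), Mt3 (-2.90), Fos, Mt2A (-2.64), Hba-a1 (-2.56), the pseudogene Arpc5l-ps1 (-2.47), Nr4a1 and Spry4 (-2.43). Values of Hba-a1, Arpc5l-ps1 and the metallothioneins are uncertain, since reads from paralogs or parent genes could be assigned to them. With the length trend removed, 124 genes were lower, and 135 of the higher and 93 of the lower genes were called both ways. Matched on length, the oxidative stress list no longer stood apart, while radial glia (2.21) and YAP and SRF targets (2.25) then did as lower and mitochondrially encoded genes (99.8) as higher. The measured median of the mitochondrially encoded list was -0.29, so it was higher only relative to genes of like length and expression.

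NL-SFMA against SFMA, the comparison of the hydrogel with both letters in its name, held the most 2-fold calls of the 3 against SFMA, both higher and lower. Some medians, such as those of erythroid and axon growth genes, were larger in size on L-SFMA. Mitochondrially encoded transcripts were higher in NL-SFMA, with a median of 1.27 and 10 of 12 past 1.5-fold, and held 5.89% of the reads against 2.68% in SFMA, 2.23% in N-SFMA and 2.33% in L-SFMA. Synaptic genes had a median of 0.94 (23 of 38 higher, 2 lower), including the glutamate receptor subunit Grin2b (1.86), the GABA receptor subunit Gabra2 (1.54) and Bsn (1.45). Adhesion genes had a median of 0.83 (29 of 43 higher, 1 lower), led by the L1 family gene Chl1 (1.88), Ncam1 (1.60), the giant cadherin Fat1 (1.58) and Alcam (1.49). Excitatory neuron genes had a median of 0.63 (12 of 21 higher, 3 lower), with Mef2c (2.01) and Nfib (1.69) higher and the progenitor factor Emx1 lower (-1.42). Axon growth genes had a median of 0.49 (24 of 50 higher, 7 lower), including Map1b (2.52), Plxna4 (2.17), Plxna2 (2.11) and Sema3c (1.95). Removing the length trend gave medians of 2.01 for mitochondrially encoded genes (12 of 12 higher), 0.38 for synapses (14 of 38 higher, 4 lower), 0.31 for adhesion (10 of 43 higher, 2 lower), 0.48 for excitatory neurons (7 of 21 higher, 2 lower) and 0.34 for axon growth (18 of 50 higher, 7 lower). Ncam1 (0.71), Fat1 (0.30), Bsn (0.31), Plxna4 (0.99) and Emx1 (-0.84) were then less than 2-fold from SFMA.

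**Figure D3:**
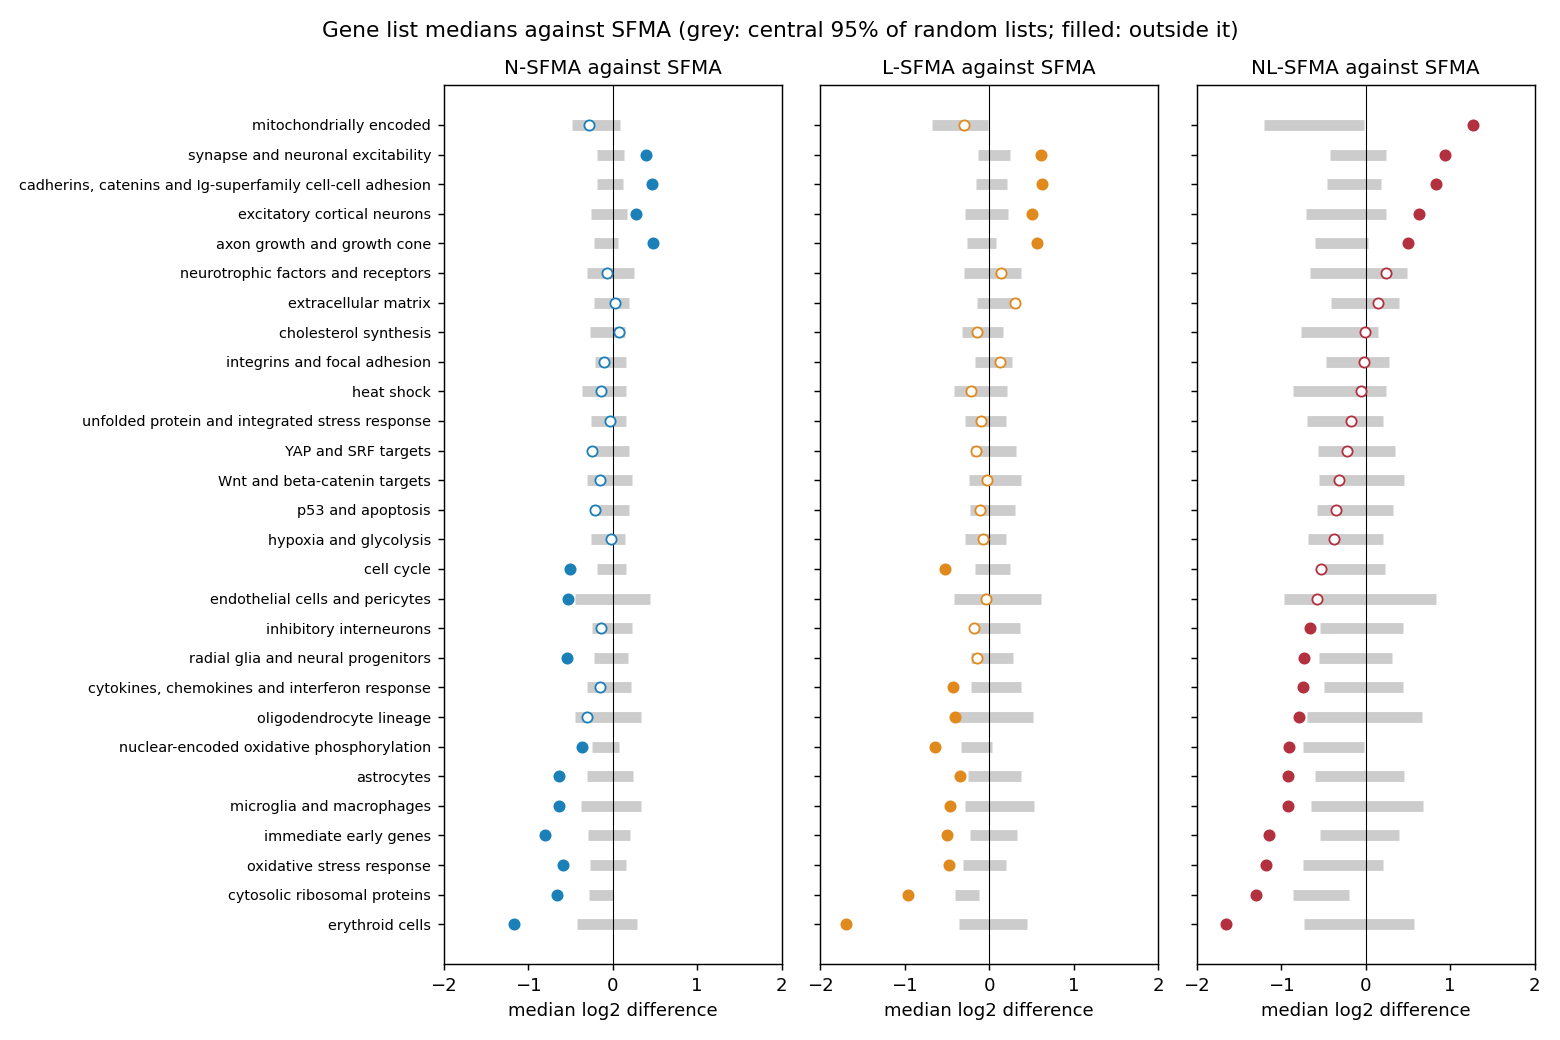
Median log2 difference of 28 gene lists for each hydrogel against SFMA (horizontal axes), with grey bars for the central 95% of matched random lists and filled points for lists outside it. The adhesion medians are 0.46, 0.62 and 0.83, and the mitochondrially encoded list is outside on the higher side in NL-SFMA, at 1.27.

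Among the lower lists on NL-SFMA, radial glia genes had a median of -0.73 (14 of 25 lower, 2 higher), including Fabp7 (-2.64), Hopx (-1.75), Emx2 (-1.30) and the stem cell factor Sox2 (-1.20). Astrocyte genes had a median of -0.92 (9 of 14 lower, 1 higher), led by Id3 (-2.39) and the lipid carrier Apoe (-1.83). Interneuron genes had a median of -0.66 (11 of 19 lower), led by the neuropeptides Sst (-2.53) and Npy (-1.72). Oligodendrocyte lineage genes had a median of -0.79 (5 of 7 lower, 1 higher) and microglia genes -0.92 (7 of 9 lower), with Lyz2 at -2.24. Erythroid genes had a median of -1.65 (8 of 8 lower), with haemoglobin genes at 0.0195% of the reads. Immediate early genes had a median of -1.14 (12 of 19 lower, 2 higher), with Fos at -3.21 and Nr4a1 at -3.04. Oxidative stress genes had a median of -1.18 (14 of 21 lower, 1 higher), including Sod1 (-1.79). Cytokine genes had a median of -0.75 (10 of 16 lower), led by Ccl3 (-1.82). Ribosomal protein genes had a median of -1.30 (42 of 45 lower) and oxidative phosphorylation genes -0.91 (25 of 38 lower), with Ndufb3 at -2.47. The p53 and apoptosis list did not stand apart, with a median of -0.35 (8 of 20 lower, 2 higher), while its members Gadd45g (-2.74), Phlda3 (-2.65), Bbc3 (-2.57) and Bax (-2.30) were lower. The cell cycle list did not stand apart either (-0.53, percentile 2.81, 14 of 32 lower, 4 higher), with Birc5 at -2.70 and the long gene Mki67 at 1.54. Corrected for the length trend, the medians were -0.37 for interneurons (9 of 19 lower, 2 higher), -0.48 for cytokines (7 of 16 lower, 1 higher) and -0.74 for ribosomal proteins (31 of 45 lower). Npy (-0.98), Sox2 (-0.93) and Mki67 (0.55) were then less than 2-fold from SFMA.

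By the size rule 1251 genes were at least 2-fold higher and 1872 lower on NL-SFMA, where counting error alone gave 3.35 and 3.89. The largest upward were the mitochondrial genes Mt-nd5 (7.95-fold, 7.78 to 8.13) and Mt-nd6 (7.46-fold, 7.08 to 7.87), which lie on opposite strands beside each other, so that their values may share reads. Map1b (5.81-fold, 5.71 to 5.92), Nexmif (2.49), Usp9x (2.43), the ubiquitin ligase Birc6 (2.39), Aff2 (2.38), the Ras inhibitor Nf1 (2.37), Qser1 (2.34) and Dync1h1 (2.33) followed. These 10 lay, with the length trend removed, between 1.08 for Dync1h1 and 3.58 for Mt-nd6, with Map1b at 1.31 and Birc6 at 1.09. The largest downward were the mitochondrial import gene Tomm7 (-3.69), Mt3 (-3.52), Uqcc2 (-3.44), Sox3 (12.2-fold, 10.1 to 14.8), Fos, Cops9 (-3.17), the histone paralog Hist1h2af (-3.16), Etv4 (-3.14), Nbl1 (-3.11) and the growth factor Mdk (8.57-fold, 8.07 to 9.10). With the length trend removed, 774 genes were higher and 1159 lower, of which 459 and 831 were also called without it. Matched on length, interneuron (11.5) and oxidative phosphorylation genes (18.9) no longer stood apart, and the cell cycle list then did as lower (1.25).

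**Figure D4:**
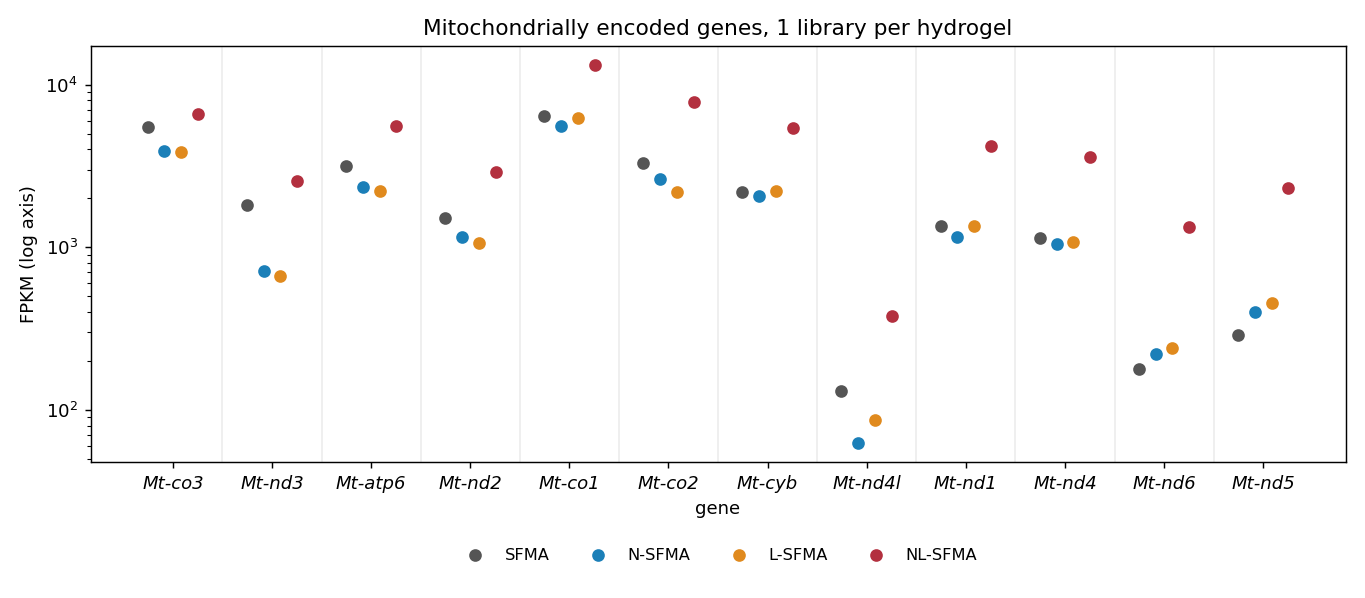
FPKM on a log axis for 12 mitochondrially encoded genes, with 1 point per library. NL-SFMA is the highest library for each gene, with folds against SFMA from 1.20 for Mt-co3 to 7.95 for Mt-nd5.

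NL-SFMA against N-SFMA asks what accompanies L where N is already present. Mitochondrially encoded genes were higher, with a median of 1.68 and 12 of 12 past 1.5-fold. By their medians, synaptic (0.48, 16 of 38 higher, 2 lower) and adhesion genes (0.47, 13 of 43 higher, 1 lower) were also higher. So were excitatory neuron (0.30, 5 of 21 higher, 2 lower) and axon growth genes (0.16, 14 of 50 higher, 7 lower). Most members of each of these lists were not past 1.5-fold. Grin2b (1.15), Chl1 (1.26), Mef2c (0.91) and Tubb2b (0.99) stood on the higher side, while the vesicle protein gene Syp (-1.38) and the actin regulator Cfl1 (-1.43) were lower. Ribosomal protein (-0.71, 24 of 45 lower) and erythroid genes (-0.48, 1 of 8 lower) had lower medians. Interneuron (-0.41, 7 of 19 lower) and cytokine genes (-0.39, 6 of 16 lower) did too. Rpl13 (-1.70), Hba-a1 (-1.29), Sst (-1.64) and Ccl3 (-1.45) led these lists. The largest differences were Mt-nd6 (6.00-fold, 5.70 to 6.31), Mt-nd4l (6.04-fold, 5.33 to 6.88), Mt-nd5 (5.78-fold, 5.67 to 5.90), the pseudogene Rps20-ps11 (1.90) and Mt-nd1 (1.87) upward. Downward they were Uqcc2 (-2.86), the pseudogene Tmsb10-ps6 (-2.56), Hist1h2af (-2.48), Timm13 (-2.41) and Bola2 (-2.39). In all 267 genes were at least 2-fold higher and 692 lower, or 382 lower with the length trend removed. Matched on length, 5 of the 9 lists still stood apart; axon growth, ribosomal protein, erythroid and interneuron genes did not. Removal of the length trend gave medians of 0.19 for synapses (9 of 38 higher, 4 lower), 0.16 for adhesion (4 of 43 higher, 2 lower), 0.15 for excitatory neurons (2 of 21 higher, 2 lower), 0.04 for axon growth (4 of 50 higher, 8 lower), -0.39 for ribosomal proteins (18 of 45 lower), -0.21 for erythroid genes (3 of 8 lower) and -0.23 for interneurons (5 of 19 lower, 1 higher), and Grin2b (0.89) and Chl1 (0.96) were less than 2-fold higher.

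NL-SFMA against L-SFMA asks what accompanies N where L is already present. By their medians, radial glia genes (-0.49, 10 of 25 lower, 0 higher) and astrocyte genes (-0.56, 6 of 14 lower) were lower, as they were on N-SFMA against SFMA. The Notch target Hes5 (-1.47), the Notch ligand Dll1 (-1.34), Insm1 (-1.07) and Btg2 (-0.85) led the first list, and Apoe (-2.27), Id3 (-1.66) and Fgfr3 (-0.95) the other. The medians of interneuron genes (-0.57, 9 of 19 lower) and ribosomal protein genes (-0.48, 17 of 45 lower, 2 higher) were lower as well. Npy (-1.73) and Rps28 (-1.52) led these lists. Mitochondrially encoded genes had a median of 1.69 (12 of 12 higher), and adhesion (0.30, 6 of 43 higher, 1 lower), synaptic (0.29, 12 of 38 higher, 3 lower), excitatory neuron (0.20, 3 of 21 higher, 4 lower) and axon growth genes (0.12, 8 of 50 higher, 9 lower) were higher by their medians. The mean of the excitatory list had the opposite sign (-0.015), with Emx1 (-1.54) and the proneural factor Neurog2 (-1.48) lower and Mef2c (1.08) higher. Corrected for the length trend, the medians were -0.034 for axon growth (2 of 50 higher, 5 lower), 0.10 for adhesion (2 of 43 higher, 3 lower), 0.18 for synapses (6 of 38 higher, 5 lower), 0.04 for excitatory neurons (1 of 21 higher, 4 lower), -0.44 for interneurons (5 of 19 lower, 1 higher) and -0.26 for ribosomal proteins (13 of 45 lower, 2 higher).

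In that comparison 108 genes were at least 2-fold higher and 851 lower, or 166 higher with the length trend removed. The largest upward were Mt-nd6 (5.53-fold, 5.27 to 5.80), Y_RNA (6.46-fold, 2.46 to 21.4), Mt-nd5 (5.07-fold, 4.97 to 5.16), Mt-nd4l (4.32-fold, 3.88 to 4.82) and Mt-nd3 (3.82-fold, 3.68 to 3.96). Y_RNA is a name shared by small RNAs that poly(A) libraries do not capture well. Downward were the stress gene Gadd45g (6.41-fold, 5.26 to 7.87), the apoptosis gene Bbc3 (6.29-fold, 5.13 to 7.77), Pfdn6 (12.1-fold, 5.35 to 34.0), Mrps26 (-2.34) and Cops9 (-2.29). Matched on length, interneuron (2.69), ribosomal protein (39.5) and axon growth genes (96.0) no longer stood apart.

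The scaling of the libraries moved the balance of these counts. The median tested gene differed by -0.10 in NL-SFMA against SFMA and by -0.13 in NL-SFMA against L-SFMA. Of all 2-fold calls, the higher ones made up 24.4% in N-SFMA, 52.2% in L-SFMA and 40.1% in NL-SFMA against SFMA, and after rescaling to TPM 60.4%, 84.2% and 61.8%. They made up 27.8% against N-SFMA and 11.3% against L-SFMA, with 45.9% after rescaling to TPM in the first and 25.4% after centring on the median gene in the other. Centring also gave 42.2% for L-SFMA against SFMA and 39.8% for NL-SFMA against N-SFMA.

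The remaining lists did not stand apart in any of the 5 comparisons before correction for length, and their medians are given in the order N-SFMA, L-SFMA and NL-SFMA against SFMA, then NL-SFMA against N-SFMA and against L-SFMA. Integrin and focal adhesion genes, which link cells to matrix, had medians of -0.10, 0.13, -0.02, 0.09 and -0.10, although Vasp was at -1.68 in NL-SFMA against SFMA. Matrix genes had medians of 0.03, 0.31, 0.15, 0.25 and -0.07, and neurotrophic factor genes of -0.07, 0.14, 0.24, 0.23 and 0.04. YAP and SRF targets had medians of -0.25, -0.16, -0.22, 0.13 and 0.04, with the actin-binding Cnn2 at -2.08, -2.41 and -2.08 against SFMA. Wnt targets had medians of -0.16, -0.02, -0.31, -0.02 and -0.12, with the cyclin Ccnd1 at -1.42, -1.21 and -1.11 against SFMA. The unfolded protein response had -0.03, -0.10, -0.18, -0.12 and -0.23, heat shock -0.14, -0.21, -0.05, -0.02 and 0.00, and p53 and apoptosis -0.21, -0.11, -0.35, -0.23 and -0.35. Hypoxia and glycolysis had -0.02, -0.07, -0.38, -0.31 and -0.23, and cholesterol synthesis 0.07, -0.14, -0.01, -0.15 and 0.01. Matched on length, integrins (0.13) and YAP and SRF targets (0.90) stood apart as lower on N-SFMA. Several of these medians changed sign with the length trend removed: matrix genes had -0.33, -0.13, -0.58, -0.12 and -0.29, integrin genes -0.19, -0.21, -0.40, -0.22 and -0.22, and neurotrophic factor genes -0.32, 0.02, -0.32, -0.02 and -0.01. Matrix and integrin genes then stood apart as lower in all 3 comparisons with SFMA, YAP and SRF targets on N-SFMA and L-SFMA, neurotrophic factor and p53 genes on N-SFMA, and Wnt targets on NL-SFMA. The unfolded protein response, heat shock, hypoxia, Wnt and cholesterol lists each changed sign in at least 1 comparison too. The 2 ways of allowing for length differed here. Among random lists matched on length, matrix genes did not stand apart against SFMA (percentiles 3.80, 23.85 and 2.93). Integrin genes did not on L-SFMA (7.53) or NL-SFMA (4.59).

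Several groups repeated across pairs of libraries that share no library. The medians of adhesion, synaptic, axon growth and excitatory neuron genes were higher in both pairs of each letter, with few members past 1.5-fold higher in both. For N these were 2 of 43, 4 of 38, 6 of 50 and 2 of 21, and for L 9, 12, 12 and 3. Of the 43 adhesion genes, 25 lay above 0 in both N pairs and 4 below 0 in both. Among the adhesion genes that led on N-SFMA, only Ncam1 was higher on NL-SFMA than on L-SFMA (105 against 79.5 FPKM). L1cam (47.4 against 51.2), Dchs1 (33.6 against 37.2) and Cntn2 (84.9 against 99.1) were lower there. In NL-SFMA against L-SFMA more axon growth and excitatory neuron genes were past 1.5-fold lower than higher. Axon growth did not stand apart in the second pair of either letter when matched on length (percentiles 96.0 for N and 91.5 for L), and its median in the second N pair was -0.034 with the length trend removed. For N, the medians of radial glia genes were lower in both pairs (-0.55 and -0.49), as were those of astrocyte genes (-0.64 and -0.56), but the members behind them differed in part. Of 25 radial glia genes 15 lay below 0 in both pairs, and of the 10 past 1.5-fold lower in each pair 4 were shared; for astrocyte genes 10 of 14 lay below 0 in both and 3 were past 1.5-fold lower in both. Slc1a3 was at 8.23 FPKM on L-SFMA and 10.6 on NL-SFMA, higher where N was added, and Dll1, at -1.34 in that pair, was 1.13-fold (0.999 to 1.28) on N-SFMA against SFMA. For L the radial glia medians were -0.15 and -0.16 and did not stand apart in either pair, although the first did as lower when matched on length or with the length trend removed (-0.31). The cytokine median was lower in both L pairs (-0.43 and -0.39), with 4 of 16 members past 1.5-fold lower in both. The ribosomal protein median was lower in both N pairs (-0.67 and -0.48) and both L pairs (-0.97 and -0.71). Of 45 ribosomal members, 12 were past 1.5-fold lower in both N pairs and 24 in both L pairs. Matched on length, the ribosomal list did not stand apart in the second pair of either letter (percentiles 39.5 and 7.06). Whether the N and L differences differ from each other was not tested. Genes at least 2-fold lower in both N pairs numbered 67, where independent lists would give 22.5, and genes higher in both numbered 9, where they would give 0.924. Those with the largest shared N difference were Nbl1 (-1.60 and -1.48), Rps28 (-1.44 and -1.52), the microglial Tyrobp (-1.66 and -1.43), Ptrhd1 (-1.50 and -1.41), the lysozyme Lyz2 (-1.64 and -1.39), Sox3 (-2.66 and -1.36), Phlda3 (-1.67 and -1.35), the ERK-regulated repressor Erf (-1.32 and -1.38), Tomm7 (-1.31 and -2.22) and Psmg4 (-1.25 and -1.46), each lower. In both L pairs 66 genes were lower and 70 higher, where independent lists would give 21.0 and 8.88. Rps28 (-1.53 and -1.61), Nbl1 (-1.63 and -1.51), Tomm7 (-1.47 and -2.38), Rpl36al, Rpl37, the interneuron peptide Sst (-1.30 and -1.64) and the pseudogenes Rpl10a-ps9 and Rps21-ps1 were lower, and Birc6 (1.54 and 1.33) and Usp34 (1.30 and 1.33) higher. Corrected for the length trend, Birc6 (0.70 and 0.67) and Usp34 (0.61 and 0.78) were past 2-fold in neither L pair, Rps28 (-0.82), Rpl36al (-0.64), Sst (-0.65), Rpl10a-ps9 (-0.66) and Rps21-ps1 (-0.55) no longer in L-SFMA, and Psmg4 (-0.82) no longer in N-SFMA. Across genes, the log2 differences of the 2 N pairs correlated at r = 0.417 with the same sign in 66.3% of genes, and those of the 2 L pairs at r = 0.505 with the same sign in 68.5%. Counting error alone gave a correlation of -0.00 for both, which follows from pairs that share no library. Differences between the libraries other than the letters could give such correlations too, and these were not separated. With the length trend removed the correlations were 0.314 and 0.350, genes lower in both pairs numbered 27 for N and 18 for L, and genes higher in both 15 and 82.

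The differences of N-SFMA and L-SFMA from SFMA, which share the SFMA library, correlated across genes at r = 0.861, where counting error with the shared SFMA library alone gave 0.476. Their covariance was 0.213 against a simulated 0.00633, and 207 genes were lower and 79 higher in both, where independent lists would give 9.98 and 3.52. Nr4a1, Fos, Etv4, Spry4, Slco1c1, Hbe1, Mt3 and Mt2A were among the 10 lowest in both. The simulated values include no spread between separate cultures, and part or all of this excess may come from the shared SFMA library, which cannot be split. The correlations of N-SFMA and L-SFMA with NL-SFMA, each against SFMA, were both 0.794, with simulated values of 0.456 and 0.462. Whole libraries correlated most closely for N-SFMA with L-SFMA (r = 0.989) and least for SFMA with NL-SFMA (r = 0.888), across genes.

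An additive model of both letters, the only comparison with more than 1 library on a side, called the progenitor factor Sox3, Nexmif and the growth factor Mdk among others. Its p-values set an effect against the N by L interaction pooled over genes, and not against a spread between cultures. For N, 452 genes rose and 510 fell at an adjusted p under 0.05 with edgeR, and for L 1051 rose and 828 fell. Sox3 (log2 fold change -2.08, adjusted p = 6.4e-09) fell with N. Nexmif (1.58, adjusted p = 2.9e-06) rose with N, and Mdk fell (-1.57, 7.1e-06). The layer-forming Reln (1.87, adjusted p = 3.0e-08) and Nexmif (1.67, 2.3e-07) rose with L, and Tomm7 fell (-2.11, 1.6e-08). Corrected for the length trend, edgeR gave smaller values for the long genes Reln with L (0.93, adjusted p = 0.025) and Nexmif with N (1.05, 0.011) and L (0.91, 0.019), which were still called. Dcx rose with N (0.97, adjusted p = 0.022) and L (1.08, 0.0048), and so did Map2 (1.02, 0.0091, and 1.05, 0.0033). Cdh2 rose with L (0.75, 0.041), while for N its value was 0.62 (adjusted p = 0.14). None of these calls of Dcx, Map2 and Cdh2 held with the length trend removed, where edgeR's adjusted p was 0.37 and 0.46 for Dcx with N and L, 0.21 and 0.37 for Map2, and 0.25 for Cdh2 with L. Each of these genes had the same direction in both pairs of libraries.

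With 1 residual degree of freedom every gene took the variance of the common trend, so a gene that differs in only 1 of the 2 pairs can pass. Etv4 did so for N (adjusted p = 2.7e-06), although its log2 difference was -3.32 without L, while both libraries with L were low, at 0.836 FPKM on L-SFMA and 0.651 on NL-SFMA. The limma test fixed beforehand called 156 and 674 genes for N and 774 and 779 for L, DESeq2 277 and 177 and 730 and 455, and limma on TPM values 1 and 15 and 367 and 68, each as higher and lower. With the length trend removed edgeR called 95 and 141 genes for N and 273 and 230 for L, of which 67, 100, 215 and 129 were also called without that step.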

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

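The tests of explanations here were all chosen after the result was seen, and Notch1 is named after its value was seen. The N or the L difference had opposite signs without and with the other letter for the values that follow, and with 1 library on each hydrogel these differences were not tested. The median N difference of the erythroid list was -1.17 without L and 0.04 with it, 1.21 apart, and that of the mitochondrially encoded list was -0.28 and 1.69, 1.97 apart. With L the erythroid list did not stand apart (percentile 73.6) and its mean was -0.005. Its positive median there shows little difference and no clear reversal. The median L difference of the mitochondrially encoded list was -0.29 without N and 1.68 with it, also 1.97 apart. The mitochondrially encoded medians no longer had opposite signs with the length trend removed, at 0.08 and 1.97 for N and 0.23 and 1.98 for L, while those of the erythroid list did (-1.08 and 0.09). Among single genes the N differences lay 3.45 apart for Hbe1, 2.62 for the pseudogene Arpc5l-ps1, 3.15 for Mt-nd4l, 2.73 for the pseudogene Rps20-ps11 and 3.28 for Mt-nd3. The L differences lay 2.73 apart for Rps20-ps11, 2.10 for Y_RNA and 3.28 for Mt-nd3. The N difference of Hbe1 with L rests on few reads, 9 in L-SFMA and 18 in NL-SFMA. Y_RNA had 16, 17, 5 and 28 reads in SFMA, N-SFMA, L-SFMA and NL-SFMA. The signs of these differences are therefore uncertain. The N and L differences share 1 interaction, so an item listed for both letters has the same value.

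Long genes were higher and short genes lower than in SFMA. A higher level of neuronal genes, many of them long, is excluded as the whole cause, since the slope of the log2 difference on log2 length persisted inside 9 lists of functions used by every kind of cell, at 0.25 in N-SFMA, 0.27 in L-SFMA and 0.53 in NL-SFMA (249 genes). A property that goes with gene length and acts on genes of every kind may contribute, as these slopes were 1.21, 1.01 and 1.26 times the slopes over all genes. RNA integrity, fragment size and transcription of long genes could each act this way and are not separated, and GC content was not analysed here. Among 35 neuronal list genes with models up to 2.5 kb, the median was 0.017, 0.035 and -0.18 as measured and 0.22, 0.25 and 0.20 with the trend removed, when 28, 27 and 20 of them lay above 0. A neuronal difference beside the trend stays open.

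Mitochondrially encoded transcripts were higher in NL-SFMA than in the other 3 libraries. The length trend is excluded as the cause, since it runs the other way for genes this short. The list's median model length was 869 bases, and genes under 1 kb had a median of -0.89 in NL-SFMA against SFMA. Removing the trend could therefore only raise the list's median, which was then 2.01. One common factor for every such transcript, as from more mitochondrial RNA in general, cannot be told apart from gene-specific changes. The SD of the log2 differences against SFMA was 0.837, which is 1.52 times the largest SD among the other 3 libraries (0.551). Against N-SFMA and L-SFMA it was 0.590 and 0.506, near that largest SD. The largest SD came from L-SFMA against SFMA, while L-SFMA against N-SFMA gave 0.200, well below all of these. The result therefore depends on which pair serves as the measure. Each SD rests on single libraries. The hydrogel cannot be told apart from a property of that library either, since 1 library was made on NL-SFMA. A response of the cells and a loss of cytoplasmic RNA may each apply, and neither was tested.

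By their list medians, radial glia and astrocyte genes were lower in N-SFMA and NL-SFMA than in SFMA. The length trend is excluded as the cause, because the highest of the 4 percentiles among random lists matched on length was 0.04. An odd SFMA library stays open: NL-SFMA against L-SFMA leaves SFMA out and gave percentiles no higher than 0.61 for the 2 lists, but these are single libraries, and only 4 of the 10 radial glia and 3 of the 8 astrocyte genes past 1.5-fold lower on N-SFMA were so there too. A lower share of radial glia with no other change stays open. In N-SFMA, 17 of 22 listed genes lay below SFMA beyond counting error and 2 above it, Eomes (2.14-fold) and Notch1 (1.32-fold), and Eomes marks intermediate progenitors. This count cannot decide, because the list was taken up for its lower median. Folds of the lower genes were unequal beyond counting error, such as 0.177 (0.164 to 0.190) for Fabp7 and 0.896 (0.838 to 0.958) for Nes. Each fold rests on single libraries. A lower level of these genes in each cell, or a difference between the cells plated, may equally apply, and neither was tested.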

How the results depend on the processing

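The length trend removal, length-matched lists, CPM, TMM of the size rule, relative log expression factors and DESeq2 were chosen after seeing the data. For 2-fold counts, 64 of the 100 values under other settings stayed within 1.5 times the reported count. Of the medians of lists that stood apart, 2 reversed, both in NL-SFMA against L-SFMA: axon growth, at -0.034 with the length trend removed, and excitatory neurons, at -0.015 for the mean in place of the median; the cause was not tested. Over all lists and settings, another 72 values moved past a margin set by the width of the random range and 1581 did not. Of 78 medians that did not stand apart, 23 changed sign with the length trend removed, among them matrix genes in NL-SFMA against SFMA (0.15 to -0.58). Of 28 lists, 5 in place of 9 stood apart in NL-SFMA against N-SFMA once random lists were also matched on length. Depth limits genes near the floor, and a single library per hydrogel limits everything else.

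The 2-fold counts below follow the order N-SFMA, L-SFMA and NL-SFMA against SFMA, then NL-SFMA against N-SFMA and L-SFMA, leaving out those that stayed within 1.5 times. At a pseudocount of 0.1 FPKM, higher genes numbered 331 and 909 for the first 2 and 629 and 283 for the last 2, and lower genes 647, 618, 1124 and 1402. At 5 FPKM they numbered 15, 62, 455, 42 and 29 higher and 127, 174, 1048, 308 and 323 lower. A larger pseudocount shrinks every ratio, so these shifts follow from its construction. Rescaled to TPM, higher genes numbered 464, 1379, 2366, 638 and 227. As CPM, higher genes numbered 274, 825, 552 and 206, without NL-SFMA against SFMA, and lower genes 512 on N-SFMA. With the length trend removed, lower genes numbered 185, 124 and 1159 against SFMA and 382 against N-SFMA, and higher genes 774 on NL-SFMA and 166 against L-SFMA. Higher genes in NL-SFMA against L-SFMA numbered 194 after centring and 192 after TMM scaling. Rescaling to TPM, centring and TMM scaling move all genes of a comparison by a common amount, apart from the pseudocount, so their shifts follow from construction too. For the CPM values and the length trend, the cause was not tested.

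The correlation of the N pairs was 0.360 and 0.452 at pseudocounts of 0.1 and 5, 0.390 unfiltered, 0.474 with the filter at 5, 0.389 in TPM and 0.314 with the length trend removed. For the L pairs these were 0.439, 0.539, 0.474, 0.557, 0.472 and 0.350. In the additive model, genes higher with N numbered 156 with limma, 89 without trend or robust fitting, 120 and 96 at pseudocounts of 0.1 and 5, 249 after centring, 1 in TPM, 277 with DESeq2 and 95 with the length trend removed. Genes lower with N numbered 15 in TPM, 177 with DESeq2 and 141 with the length trend removed. Genes higher with L numbered 562 without trend or robust fitting, 694 and 694 at the pseudocounts, 367 in TPM and 273 with the length trend removed. Genes lower with L numbered 68 in TPM, 455 with DESeq2 and 230 with the length trend removed. For these, the cause was not tested.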

Other observations

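The comparison of L-SFMA with N-SFMA and the FGF target test were chosen after the data were seen, and Etv5, Spry2 and Spred1 are named after their values were seen. L-SFMA and N-SFMA were the closest pair of libraries, with 47 genes at least 2-fold higher on L-SFMA and 31 lower. Among random lists matched on expression, the median log2 difference stood apart as higher on L-SFMA for radial glia genes (0.33, 4 of 25 past 1.5-fold), astrocyte genes (0.30, 3 of 14), matrix genes (0.34, 2 of 24, 1 lower), adhesion genes (0.25, 3 of 43), axon growth genes (0.14, 2 of 50, 1 lower), endothelial and pericyte genes (0.54, 2 of 5) and mitochondrially encoded genes (0.08, 0 of 12). It stood apart as lower for erythroid genes (-0.48, 4 of 8) and cytokine genes (-0.14, 4 of 16). The medians of ribosomal protein (-0.31), oxidative phosphorylation (-0.25) and cholesterol synthesis genes (-0.14) also lay below those of random lists, with 0 of 45, 0 of 38 and 0 of 23 members past 1.5-fold. The interneuron median of -0.04 (0 of 19) did so too, but not when lists were matched on length. The matrix (0.20), astrocyte (0.23), axon growth (0.04) and interneuron lists (0.02) no longer stood apart with the length trend removed. The log2 difference correlated with log2 model length at r = 0.25 across genes.

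Etv4, Etv5 and Spry4, which FGF signalling through ERK is known to switch on, were all lower than in SFMA. Etv5 differed by -2.25 in N-SFMA, -1.86 in L-SFMA and -1.97 in NL-SFMA. Lower FGF and ERK signalling is a hypothesis for this, and it was tested on 11 other known targets not looked at singly before, of which 10 had enough expression; Dusp4, Dusp5 and Fosl1 also stand in the immediate early list, which was lower in all 3 comparisons. Among random lists matched on expression and length, their median lay at percentile 0.89 in N-SFMA (-0.20) and 2.36 in NL-SFMA (-0.26). Lower signalling would give such low percentiles, but both comparisons use the same SFMA library and are not separate evidence. In L-SFMA their median lay at percentile 31.4 (0.21), where the test left the hypothesis open. In each comparison 2 of the 10 were past 1.5-fold lower, with Spry2 among them (-1.02, -0.94 and -1.34), and Spred1 was higher in NL-SFMA (1.03). In the pair that leaves SFMA out, Etv4 was at 0.836 FPKM on L-SFMA and 0.651 on NL-SFMA. Etv5 was at 8.40 and 7.68 there, and Spry4 at 0.602 and 0.541. A response spread over a few targets, a change at these 3 genes from another cause, or an odd SFMA library may account for the lower values as well.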
